A study of Homo sapiens with 22 samples.

How the data were processed

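The study measured RNA in HN-6 cells, a human head and neck squamous carcinoma line, by sequencing of poly(A)-selected, stranded libraries. All 22 libraries came from cells given interferon-β at 1000 U/ml for 24 h, so there was no untreated baseline. There were 8 groups in 4 separately deposited tables. SMYD3, a lysine methyltransferase, was depleted in 3 ways: in 1 knockout clone against the parental line (3 libraries each), with 1 siRNA against a negative control siRNA (3 each), and with 1 antisense oligonucleotide (ASO) against phosphate-buffered saline, PBS (2 each). UHRF1, a protein that guides maintenance DNA methylation, was depleted with an siRNA against its own negative control siRNA (3 each). Knockdown lasted 72 h. The study calls the replicates biological. The labels do not say that a replicate number marks a shared day or batch, so no pairing was used.

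The authors' notes name the hg38 genome build, bcl2fastq and Bowtie. Their versions, the role of each tool, the counting tool and the annotation release are not given in the sources used here. The SMYD3 siRNA, ASO and UHRF1 siRNA tables hold counts as deposited, whole numbers per gene. The knockout table, as deposited, holds a signal and no raw counts: gene counts that the authors divided by 1 factor per library. Dividing each column by its smallest step gave whole reads for 100% of the values within 0.01. In knockout replicate 1 the step is 0.991, so close to 1 that an automatic test for whole reads passes over it. The knockout table lists 17382 gene symbols against 57218 to 59020 in the others, under a filter that is not stated. The ASO and UHRF1 siRNA tables hold 0 reads for every mitochondrial gene. The SMYD3 siRNA table had 23588 lines without a symbol, which carried 0.849% to 0.917% of its reads and were named by Ensembl identifier where the annotation had it. Lines with the same symbol were summed. The annotation used for positions was GENCODE release 29 on GRCh38, which may differ from the one the authors used.

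Total reads in genes ranged from 24777802 to 47690298 per library in the knockout table (recovered reads), from 32441991 to 54121262 in the SMYD3 siRNA table, from 30792923 to 32045158 in the ASO table and from 57588142 to 62921144 in the UHRF1 siRNA table. Group means are given with the standard deviation (SD) between libraries, and log2 fold changes with the standard error (SE) of the fit. Bounds from reads cover counting error only.

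Each comparison was fitted alone on its own table. The count tables were tested with edgeR 4.0.16 (filterByExpr by group, TMM factors, robust quasi-likelihood F-test, two-sided). Before the data were examined the same test was planned for the knockout table. As its values are not counts, it was instead tested with limma 3.58.1 (trend and robust options) on log2(value + 1), for genes with a value of 10 or more in at least 3 libraries; edgeR on the recovered reads became an alternative chosen after seeing the data. P-values were adjusted by the Benjamini-Hochberg method, and genes below 0.05 count as called. R was version 4.3.3 and Python 3.11.15. Chance puts all libraries of 1 group above or below the other in 10% of genes with 3 libraries against 3.

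Before the data were examined 25 gene lists were fixed: type I interferon response; interferon receptor, JAK-STAT and IRF factors; nucleic acid sensors and adaptors; MHC class I and class II antigen presentation; chemokines and cytokines; immune checkpoint ligands; DNA methylation and repressive chromatin; other SMYD family members; DNA replication; mitosis; germline genes silenced by DNA methylation; p53 targets; NF-kB feedback targets; keratinocyte differentiation; basal squamous epithelium; mesenchymal and extracellular matrix; unfolded protein and integrated stress response; cholesterol synthesis and uptake; hypoxia response; ERK pathway output; leukocyte, fibroblast and endothelial markers; and replication-dependent histones. Each list with 5 or more tested members was tested with camera (limma, preset correlation 0.01), adjusted over the lists, and again with an estimated correlation and with fry as alternatives. The genes named in the text were set by a rule: SMYD3, UHRF1 and 11 genes chosen in advance; the 4 called members of each list with the largest absolute change; the 5 largest rises and 5 largest falls among called genes with a mean log2 CPM of 1 or more and no overlap between groups; and the 10 genes per direction with the largest smallest change over the 3 SMYD3 comparisons. Some genes that this rule names are not reported here.

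Overlaps between comparisons were set against the number expected of independent lists and tested with one-sided Fisher's exact tests over genes. The difference between 2 log2 fold changes was tested as a contrast. For the pairs without the knockout this was edgeR on the 16 count libraries. For the pairs with the knockout it was limma on log2(CPM + 1) of the knockout, SMYD3 siRNA and ASO libraries. Mitochondrial genes were left out of these joined tables. No level was compared across tables. Other alternatives were DESeq2 1.42.0, RLE and upper quartile factors, other low-count filters, a test against a log2 fold change of 0.5, the replicate number as a block, and leaving out each library in turn.

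The tests were tested on simulated data with 100 genes changed by 1.5-fold and 100 by 2-fold. The changed genes were drawn from those at a mean CPM of 2 or more, and as many rose as fell. Of the 2-fold changes, 100% were recovered in the knockout layout, 97% in that of the SMYD3 siRNA, 99% in that of the ASO and 100% in that of the UHRF1 siRNA. Of the 1.5-fold changes 93%, 86%, 89% and 93% were recovered, in the same order. Unchanged genes made up 20 of 213, 11 of 194, 17 of 205 and 7 of 200 calls, in the same order. All other genes were left unchanged, and the knockout values were scaled by the simulated library sizes. The shares recovered thus do not cover genes with few reads or errors of scaling.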

Results

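The data are gene-level RNA measurements from 22 libraries of HN-6, a human head and neck squamous carcinoma line, all from cells given interferon-β at 1000 U/ml for 24 h. They form 8 groups in 4 comparisons, each with its own control: a SMYD3 knockout clone against the parental line (3 libraries each), a SMYD3 siRNA against a control siRNA (3 each), a SMYD3 antisense oligonucleotide (ASO) against PBS (2 each) and a UHRF1 siRNA against a control siRNA (3 each). Reads in genes ranged from 24777802 to 47690298 per library in the knockout comparison, from 32441991 to 54121262 with the SMYD3 siRNA, from 30792923 to 32045158 with the ASO and from 57588142 to 62921144 with the UHRF1 siRNA. The study asks whether depletion of SMYD3 raises type I interferon response and antigen presentation genes in these cells, and whether UHRF1 has a part in it. SMYD3 is a protein-coding gene on chromosome 1 (GRCh38, from 245749342 to 246507312, minus strand) with several annotated noncoding genes inside its span. UHRF1 lies on chromosome 19 (from 4903080 to 4962154, plus strand).

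The targeted transcripts were lower in every treated library than in every control library. SMYD3 fell from a mean of 321.9 ± 18.3 (SD, n = 3, deposited normalized count) in parental cells to 93.6 ± 18.5 (SD, n = 3) in the knockout clone. With the SMYD3 siRNA it fell from 15.1 ± 1.72 to 2.85 ± 0.207 CPM (read counts scaled by library total; SD, n = 3 each). With the ASO SMYD3 fell from 21.5 ± 0.686 to 3.74 ± 0.639 CPM (SD, n = 2 each). UHRF1 fell from 64.5 ± 1.73 to 2.23 ± 0.420 CPM with its siRNA (SD, n = 3 each). Reads over the whole gene do not show whether the transcript left in the knockout clone codes for protein.

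**Figure D1:**
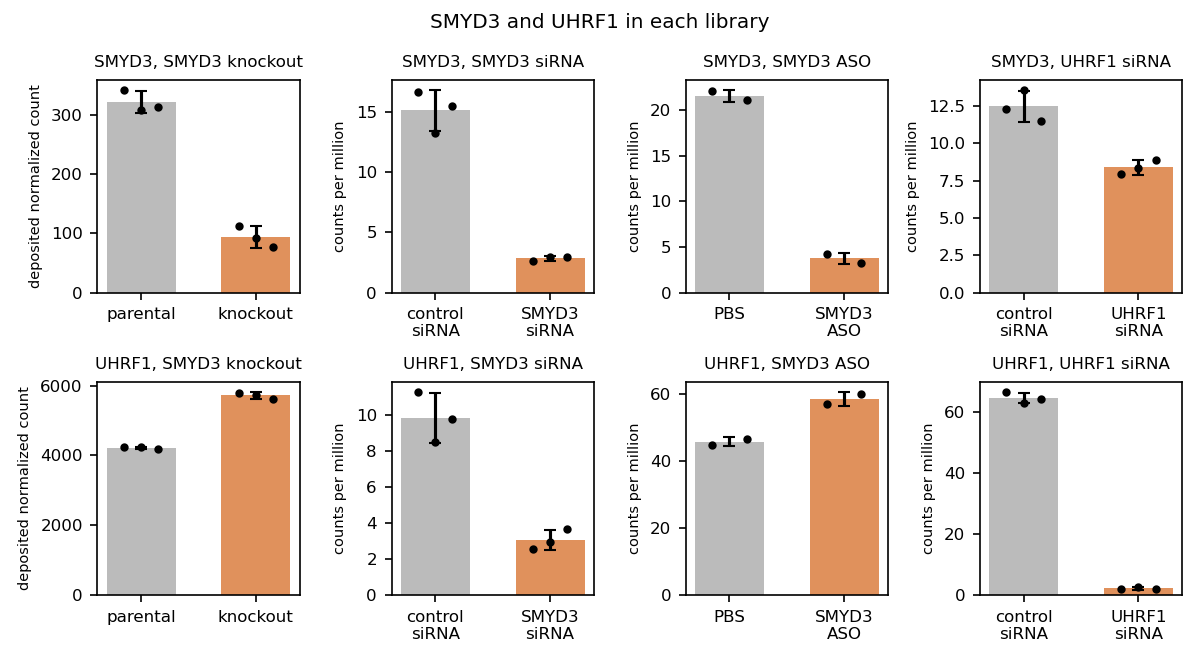
SMYD3 (top) and UHRF1 (bottom) in each library of the 4 comparisons; the y axis is the deposited normalized count for the knockout and CPM elsewhere. Bars are group means, error bars are the SD between libraries and points are single libraries; SMYD3 in the knockout libraries averages 93.6 against 321.9 in parental libraries.

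The knockout comparison asks how a clone edited at SMYD3 differs from its parental line under interferon-β. Interferon response genes were higher in the clone: of 50 listed genes 45 rose and 2 fell, with a median log2 fold change of 1.47. RSAD2, an antiviral enzyme, rose by 4.85 ± 0.19 (log2, SE, n = 3 each), and CMPK2, its genomic neighbour, by 4.14 ± 0.26. IRF9, a transcription factor of the interferon response, fell by 0.16 ± 0.03. UHRF1 rose by 0.44 ± 0.03 (0.16 with upper quartile factors) and DNMT1, the maintenance DNA methyltransferase, by 0.91 ± 0.04. In all 16934 genes tested by limma, 7132 were higher and 7209 lower at an adjusted p under 0.05, and 2430 were higher and 3752 lower by an absolute log2 fold change of 1 or more. That split became 1561 and 4911 with upper quartile factors, and 2128 and 2260 among genes with 10 or more in every library. The groups did not overlap in 85.8% of genes, where chance gives 10%.

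Other immune groups moved with the interferon list in the clone. Nucleic acid sensors rose in 11 of 14 genes and fell in 2, with ZBP1, a sensor of Z-form nucleic acid, up by 3.41 ± 0.19 and RIGI, a sensor of viral RNA, by 3.08 ± 0.07. MHC class I presentation genes rose in 15 of 21 and fell in 3. The peptide transporter genes TAP1 and TAP2 rose by 1.84 ± 0.05 and 1.83 ± 0.04. PSMB9, an immunoproteasome subunit, rose by 0.50 ± 0.04, whereas B2M, the invariant light chain, changed by -0.03 ± 0.04 (adjusted p = 0.375). Chemokines and cytokines rose in 14 of 19 tested genes and fell in 2; CXCL10 and CXCL11, which attract T cells, rose by 5.64 ± 0.17 and 4.85 ± 0.14. Checkpoint ligands rose in 9 of 11 and fell in 2, with CD274 (PD-L1) up by 3.02 ± 0.07. By camera the adjusted p was 1.48e-08 for the interferon list, 0.0170 for the sensors, 0.0145 for MHC class I, 7.28e-04 for chemokines and 0.0229 for checkpoint ligands. These calls were lost at adjusted p = 0.503, 0.505, 0.352, 0.234 and 0.245 with an estimated correlation, in the same order. The JAK-STAT list, with 13 genes higher and 7 lower of 20, and MHC class II, with 1 higher and 4 lower of 9, were not called.

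Growth and epithelial groups also differed between clone and parental line. ERK pathway output genes rose in 17 of 18, among them AREG and EREG, ligands of the epidermal growth factor receptor, by 4.18 ± 0.11 and 3.93 ± 0.11. Basal squamous genes rose in 14 of 17 and fell in 2, with keratin KRT6A up by 5.42 ± 0.11 and the collagen COL17A1 by 2.56 ± 0.04. DNA replication genes rose in 33 of 36 and fell in 1 (ORC1 rose by 1.92 ± 0.05), NF-kB feedback genes rose in 11 of 15 and fell in 4 (TNFAIP3 rose by 2.29 ± 0.05), and unfolded protein and stress response genes rose in 16 of 20 (TRIB3 by 2.35 ± 0.04). Replication-dependent histones, whose transcripts mostly lack a poly(A) tail, fell in 9 of 10, H1-2 by 3.29 ± 0.05 on the log2 scale. In camera tests the adjusted p was 1.06e-05 for ERK output, 7.28e-04 for basal genes, 6.91e-07 for replication, 0.0180 for NF-kB, 5.79e-05 for the stress response and 7.28e-04 for histones. These calls were lost at adjusted p = 0.184, 0.184, 0.253, 0.234, 0.234 and 0.184 with an estimated correlation, in the same order.

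Other lists in the knockout had no camera call. Mitosis had 17 genes higher and 8 lower of 27, mesenchymal genes 13 and 6 of 21, germline genes 7 and 3 of 12, leukocyte markers 4 and 2 of 6 and fibroblast markers 1 and 4 of 5. Endothelial markers (0 and 1 of 2) and other SMYD genes (2 and 1 of 3) were too few to test. SMYD4 and SMYD5 rose by 1.01 ± 0.07 and 1.12 ± 0.05. SMYD2 was called at -0.16 ± 0.07, but not with DESeq2 (adjusted p = 0.0887), nor without knockout replicate 2 or 3 or any parental library (adjusted p = 0.0605 to 0.191). The medians of 5 lists changed sign with upper quartile factors: DNA methylation and repressive chromatin (14 higher and 10 lower of 28; DNMT3A and DNMT3B, the de novo methyltransferases, fell by 1.54 ± 0.08 and 1.36 ± 0.07), p53 targets (10 and 7 of 20), keratinocyte differentiation (5 and 6 of 13), cholesterol (10 and 8 of 20) and hypoxia (9 and 7 of 17). Counts adjusted over the list alone were the same as those over all genes for every list in this comparison.

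The largest single rise was SERPINB2, a serine protease inhibitor, from 1.41 ± 2.44 to 3116 ± 134 normalized counts. ABCF2-H2BK1 followed at 7.85 ± 0.52, IL24, a cytokine gene, at 6.40 ± 0.30 and AL591806.3 at 6.35 ± 0.83. INO80B-WBP1, a read-through gene, passed at 6.02 ± 1.73, but not without any of the 3 knockout libraries or parental replicate 1 or 2 (adjusted p = 0.0760 to 0.0847), nor with DESeq2 (4.12, adjusted p = 0.0822). Genes read at 0 in all 3 knockout libraries were AC087190.3, at least 580.1-fold lower, KCTD12, at least 366-fold lower, and TBC1D3H, at least 282-fold lower, against a floor of 3 reads over the group. TBC1D3H belongs to a family of near-identical copies, among which reads are hard to assign. AC087190.3 had 0 reads in every library of the other 3 tables, and TBC1D3H and INO80B-WBP1 had at most 1 read per group there. ABCF2-H2BK1 had at most 4 reads per group with the ASO and the UHRF1 siRNA and no line in the SMYD3 siRNA table, and AL591806.3 had 3 to 17 reads per group in the 3. These 5 changes were not separated from the way reads were assigned to genes. ACSS3 fell by 7.47 ± 0.41 and CP, ceruloplasmin, by 7.22 ± 0.28.

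Mitochondrial genes took 15.3 ± 0.402% of reads in parental libraries and 4.85 ± 0.0345% in knockout libraries (SD, n = 3 each). Upper quartile factors, with edgeR on recovered reads, moved the median of all genes by -0.28, to 5380 genes higher and 9118 lower. With TMM factors edgeR on recovered reads moved it by -0.03. Under upper quartile factors the interferon list's median went from 1.47 to 1.19, with 45 genes higher. PSMB9 then rose by 0.22, while IRF9 fell by 0.44 and B2M by 0.32. MHC class I became 12 higher and 6 lower with a median of 0.13 (0.42 before), JAK-STAT 11 and 8 with 0.20 (0.48), sensors 10 and 3 with 0.40 (0.68), MHC class II 0 and 6 with -0.76 (-0.33), DNA replication 27 and 4 with 0.53 (0.81), mitosis 11 and 11 with 0.00 (0.28), germline genes 6 and 5 with 0.08 (0.36) and mesenchymal genes 10 and 8 with 0.23 (0.51). Genes on chromosome 9 had a median log2 fold change of 0.58, with 72.5% of 498 genes higher, and chromosome 13 one of -0.32; with the SMYD3 siRNA, the ASO and the UHRF1 siRNA chromosome medians lay between -0.07 and 0.09.

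**Figure D2:**
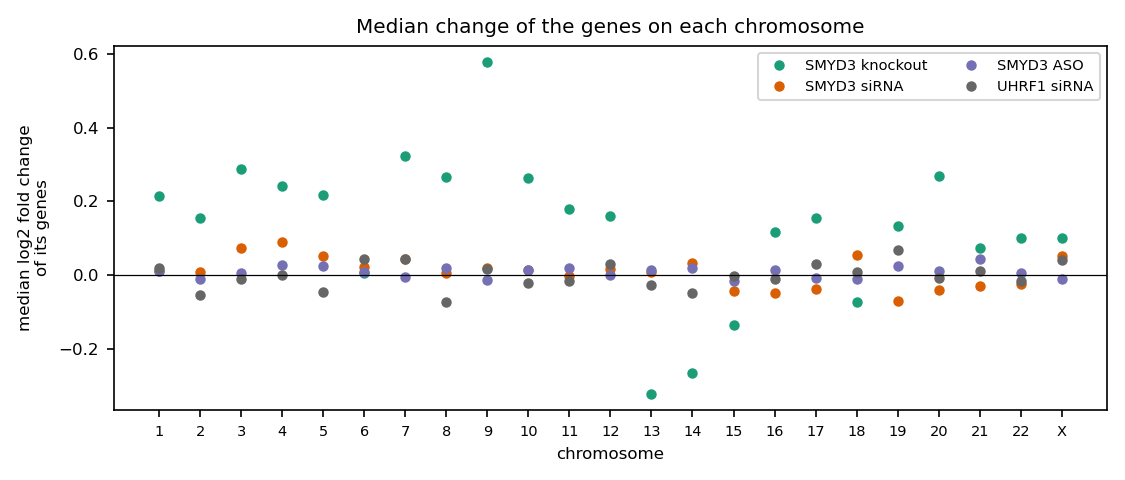
Median log2 fold change (y axis) of the genes on each chromosome (x axis) in the 4 comparisons, 1 point per chromosome and comparison. Knockout points spread from -0.32 on chromosome 13 to 0.58 on chromosome 9, and the points of the other comparisons lie close to 0.

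The SMYD3 siRNA comparison asks the same of a short depletion without clonal selection. Interferon response genes rose in 30 of 50 and fell in 3, with a median log2 fold change of 0.36. RSAD2 rose by 1.28 ± 0.10 and IFIT2, an antiviral RNA-binding protein, by 0.96 ± 0.11. All 27 mitosis genes fell, with a median of -1.33, and 23 of 36 DNA replication genes fell while 3 rose. UHRF1 fell by 1.68 ± 0.14 on the log2 scale, from 9.83 ± 1.39 to 3.05 ± 0.566 CPM (SD, n = 3 each). By edgeR, 4584 of 18964 genes were higher and 4630 lower, and 607 and 880 passed an absolute log2 fold change of 1. The groups did not overlap in 56.8% of genes, where chance gives 10%.

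The camera adjusted p was 2.97e-05 for the interferon list, 4.58e-11 for mitosis and 2.45e-04 for DNA replication. These were lost at adjusted p = 0.534, 0.534 and 0.623 with an estimated correlation, in the same order. NUF2, a kinetochore protein, fell by 2.76 ± 0.19, CDC20, an activator of mitotic exit, by 2.25 ± 0.21 and E2F1, a transcription factor of S-phase entry, by 1.45 ± 0.12. MHC class I genes rose in 12 of 21 and fell in 3; ERAP1, the peptide-trimming enzyme, rose by 1.53 ± 0.08 and TAP1 by 0.34 ± 0.09. PSMB9 (-0.04 ± 0.08, adjusted p = 0.667) was not called. B2M was called at 0.31 ± 0.10, but not without control replicate 1 (adjusted p = 0.0558) or 2 (adjusted p = 0.0659). IRF9, at -0.19 ± 0.11, was called only without SMYD3 siRNA replicate 1 (-0.30, adjusted p = 0.0242), and DNMT1 was not called at 0.06 ± 0.09. MHC class II genes rose in 8 of 10, HLA-DRA by 1.18 ± 0.11. Chemokines and cytokines rose in 12 of 23 and fell in 4, with CXCL10 up by 2.54 ± 0.12, CXCL9 by 2.77 ± 0.19 and CXCL11 by 1.79 ± 0.09. Sensors rose in 10 of 14 and fell in 2, with RIGI up by 0.79 ± 0.09. JAK-STAT genes rose in 10 of 20 and fell in 1, with IFNGR1, an interferon-γ receptor chain, up by 0.88 ± 0.07. By camera the adjusted p was 0.00725 for MHC class I, 5.23e-04 for class II, 0.00725 for chemokines, 0.00725 for sensors and 0.0225 for JAK-STAT. These were lost at adjusted p = 0.534, 0.280, 0.534, 0.280 and 0.534 with an estimated correlation, in the same order.

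NF-kB feedback genes rose in 13 of 15 with the SMYD3 siRNA and fell in 1 (TNFAIP3 rose by 1.51 ± 0.10), p53 targets rose in 14 of 21 and fell in 3 (CDKN1A, a cell-cycle inhibitor, rose by 0.82 ± 0.08), and stress response genes rose in 11 of 20 and fell in 2 (SLC7A11, a cystine transporter, rose by 1.73 ± 0.11). Fibroblast markers rose in 4 of 6, LUM by 1.25 ± 0.09, and hypoxia genes rose in 10 of 18 and fell in 3, with the glucose transporter SLC2A3 up by 3.12 ± 0.13. In camera tests the adjusted p was 2.45e-04 for NF-kB, 0.0130 for p53, 0.0176 for the stress response, 0.00725 for fibroblast markers and 0.0402 for hypoxia. These were lost at adjusted p = 0.534, 0.534, 0.534, 0.280 and 0.534 with an estimated correlation, in the same order. The hypoxia call also ended without control replicate 1 (adjusted p = 0.0724), SMYD3 siRNA replicate 2 (adjusted p = 0.0902) or 3 (adjusted p = 0.0555). Not called were ERK output (5 higher and 10 lower of 18), checkpoint ligands (3 and 3 of 11, with CD274 up by 0.75 ± 0.08 and NT5E, the enzyme CD73, down at -1.49 ± 0.09), repressive chromatin (2 and 6 of 28), germline genes (2 and 3 of 10), keratinocyte (4 and 6 of 13), basal (7 and 3 of 18; called without SMYD3 siRNA replicate 1 at adjusted p = 0.0423), mesenchymal (10 and 5 of 22), cholesterol (6 and 5 of 20), leukocyte (2 and 3 of 7) and histone genes (4 and 5 of 11). Endothelial markers (1 and 1 of 4) and other SMYD genes (0 and 2 of 3) were too few to test.

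Adjusted over the list alone, the interferon counts with the SMYD3 siRNA became 31 higher and 4 lower, JAK-STAT 10 and 2, sensors 11 and 2, checkpoint ligands 3 and 4, repressive chromatin 2 and 4, keratinocyte 5 and 6, mesenchymal 11 and 6, hypoxia 11 and 3, fibroblast markers 5 and 0 and endothelial markers 1 and 2, and the rest were the same. The largest rises were ICAM4, an adhesion molecule, at 4.15 ± 0.23, FLG-AS1 at 3.54 ± 0.15, SLC2A3, the cytokine TNFSF14 at 2.94 ± 0.11 and the fatty acid receptor CD36 at 2.87 ± 0.16. The largest falls were RPS6KL1 at -3.37 ± 0.12, PLA2G2F at -2.85 ± 0.15, NKX1-2 at -2.81 ± 0.19, NUF2 and MAD2L1, a spindle checkpoint protein, at -2.76 ± 0.17. Ribosomal protein genes took 1.81 ± 0.0567% of reads in control libraries and 1.47 ± 0.0506% in SMYD3 siRNA libraries, and mitochondrial genes 8.08 ± 1.91% and 6.15 ± 0.555% (SD, n = 3 each), with control replicate 3 at 10.2% and the other controls at 6.63% and 7.35%. Without mitochondrial genes 605 and 878 genes passed an absolute log2 fold change of 1. Only 1 siRNA sequence was used, so effects of its sequence on other transcripts were not separated from those of SMYD3.

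The ASO comparison asks the same with another chemistry. All 50 interferon response genes rose, with a median log2 fold change of 0.98. RSAD2 rose by 3.11 ± 0.07, CMPK2 by 2.49 ± 0.06 and CXCL10 by 3.45 ± 0.10 (log2, SE, n = 2 each). MHC class I genes rose in 17 of 21 and none fell, with TAP1 up by 1.07 ± 0.06. UHRF1 rose by 0.36 ± 0.06, from 45.8 to 58.6 CPM. By edgeR, 2070 of 18228 genes were higher and 1880 lower, and 182 and 101 passed an absolute log2 fold change of 1.

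The camera adjusted p was 5.06e-35 for the interferon list and 2.24e-08 for MHC class I. Both were lost at adjusted p = 0.240 with an estimated correlation. IRF9 rose by 0.43 ± 0.06, PSMB9 by 0.52 ± 0.05, B2M by 0.33 ± 0.06 and CD274 by 0.78 ± 0.07. CXCL9 (1.38 ± 0.48, adjusted p = 0.0575) and DNMT1 (0.00 ± 0.08, adjusted p = 0.993) were not called. Sensors rose in 10 of 14 and fell in 1 (ZBP1 rose by 2.38 ± 0.07), JAK-STAT genes rose in 10 of 20 (IRF7, a regulator of interferon genes, by 0.84 ± 0.06), chemokines and cytokines in 15 of 21 (CXCL11 by 2.31 ± 0.14) and checkpoint ligands in 7 of 11 (IDO1, a tryptophan-degrading enzyme, by 1.72 ± 0.10). By camera the adjusted p was 6.24e-06 for sensors, 4.90e-04 for JAK-STAT, 2.23e-09 for chemokines and 8.58e-05 for checkpoint ligands. These were lost at adjusted p = 0.240, 0.267, 0.253 and 0.240 with an estimated correlation, in the same order.

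Other gene groups moved with the ASO as well. Hypoxia genes rose in 15 of 18 (BNIP3 by 0.91 ± 0.06), histones in 10 of 10 (H2BC12 by 0.82 ± 0.06), ERK output in 10 of 18 (EPHA2 by 0.47 ± 0.06), NF-kB in 8 of 15 with 2 lower (NFKBIA rose by 0.68 ± 0.11) and stress response genes in 9 of 20 with 1 lower (PSAT1 rose by 0.50 ± 0.08). DNA replication genes rose in 16 of 36 (PCNA, the replication clamp, by 0.43 ± 0.06), while mitosis genes fell in 10 of 27 (KIF20A by 0.38 ± 0.06). In camera tests the adjusted p was 1.57e-07 for hypoxia, 1.57e-07 for histones, 5.63e-04 for ERK, 0.00316 for NF-kB, 0.00643 for the stress response, 1.39e-05 for replication and 8.98e-04 for mitosis. These were lost at adjusted p = 0.253, 0.240, 0.240, 0.240, 0.240, 0.567 and 0.481 with an estimated correlation, in the same order. The basal list (4 higher of 17, adjusted p = 0.0367) was lost at adjusted p = 0.483 with an estimated correlation, without PBS replicate 1 (adjusted p = 0.139) and without ASO replicate 2 (adjusted p = 0.125). Not called were MHC class II (3 higher of 10, but called without ASO replicate 2 at adjusted p = 0.0231), repressive chromatin (3 higher and 5 lower of 28), germline genes (5 and 1 of 10), p53 targets (8 and 2 of 21), keratinocyte (3 and 1 of 10), mesenchymal (3 and 5 of 22), cholesterol (2 and 5 of 20) and leukocyte genes (1 and 1 of 7). Fibroblast markers (0 and 2 of 4), endothelial markers (0 and 0 of 4) and other SMYD genes (1 and 0 of 3) were too few to test.

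Adjusted over the list alone, the ASO counts became 19 higher for MHC class I, 10 higher and 1 lower for JAK-STAT, 17 and 1 for chemokines, 8 and 0 for checkpoint ligands, 6 and 6 for repressive chromatin, 19 and 0 for replication, 0 and 11 for mitosis, 6 and 3 for germline genes, 9 and 2 for p53 targets and for NF-kB, 6 and 0 for basal genes and 3 and 1 for leukocyte markers, and the rest were the same. After SMYD3 the largest falls were CYP1A1, a target of the aryl hydrocarbon receptor, at -1.47 ± 0.18, AL772337.3 at -1.36 ± 0.16, EGR3 at -1.25 ± 0.10 and ACO1 at -1.22 ± 0.09. The control was PBS and not another oligonucleotide, and DESeq2 called 2259 genes where edgeR called 3950. With the replicate number as a block edgeR called more genes, as given with the alternatives below. By an absolute log2 fold change of 1 or more DESeq2 had 114 higher and 31 lower, and edgeR without ASO replicate 1 had 194 and 184. Without 1 library the number of genes called ranged from 2738 to 4118.

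The UHRF1 siRNA comparison asks which of these changes follow loss of UHRF1. All 36 DNA replication genes and all 27 mitosis genes fell, with medians of -2.49 and -2.92. GINS2, a part of the replicative helicase, fell by 4.67 ± 0.10 and TYMS, which makes thymidylate, by 4.01 ± 0.06 (log2, SE, n = 3 each). Interferon response genes rose in 46 of 50 and fell in 2, with a median of 0.52 and IFIT2 up by 2.98 ± 0.06. SMYD3 fell by 0.57 ± 0.09 and DNMT1 by 0.78 ± 0.05. By edgeR, 5873 of 18341 genes were higher and 5986 lower, and 1360 and 1908 passed an absolute log2 fold change of 1. The groups did not overlap in 68.1% of genes, where chance gives 10%.

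The camera adjusted p was 3.43e-19 for DNA replication, which held at adjusted p = 0.0334 with an estimated correlation. It was 2.38e-16 for mitosis and 8.09e-11 for the interferon list, both lost at adjusted p = 0.135 with an estimated correlation. RSAD2 rose by 1.70 ± 0.05, IRF9 by 0.36 ± 0.07 and CD274 by 0.94 ± 0.05. JAK-STAT genes rose in 18 of 20 and fell in 1 (STAT2, a transcription factor of the interferon response, rose by 0.89 ± 0.05), sensors rose in 12 of 14 (IFIH1, a sensor of long double-stranded RNA, by 1.18 ± 0.05), chemokines rose in 14 of 21 and fell in 5 (CCL5, which attracts T cells, rose by 3.84 ± 0.08, CXCL10 by 1.58 ± 0.08) and NF-kB genes rose in 13 of 15 and fell in 1 (TRAF1 rose by 2.43 ± 0.06). By camera the adjusted p was 3.70e-05 for JAK-STAT, 6.38e-05 for sensors, 0.0148 for chemokines and 3.70e-05 for NF-kB. These were lost at adjusted p = 0.0954, 0.135, 0.628 and 0.117 with an estimated correlation, in the same order.

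MHC class I genes went both ways with the UHRF1 siRNA, 12 higher and 7 lower of 21, without a camera call: TAP1 rose by 0.65 ± 0.05, and B2M fell by 0.74 ± 0.06. PSMB9 was called at 0.16 ± 0.05, but not without control replicate 3 (0.13, adjusted p = 0.0558). ERK output fell in 12 of 18 and rose in 4 (DUSP6, a phosphatase acting on ERK, fell by 1.65 ± 0.06), and cholesterol genes rose in 11 of 20 and fell in 5 (HMGCS1 rose by 1.41 ± 0.05). In camera tests the adjusted p was 0.0251 for ERK and 0.0437 for cholesterol. They were lost at adjusted p = 0.517 and 0.471 with an estimated correlation, and the cholesterol call also without control replicate 3 (adjusted p = 0.0671).

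Not called with the UHRF1 siRNA were MHC class II (3 higher and 4 lower of 10), checkpoint ligands (7 and 4 of 11), repressive chromatin (9 and 15 of 28, with DNMT3B down at -2.49 ± 0.09), germline genes (1 and 6 of 9), p53 targets (8 and 8 of 20), keratinocyte (6 and 2 of 13), basal (9 and 6 of 17), mesenchymal (10 and 8 of 22), hypoxia (6 and 9 of 18), leukocyte (3 and 2 of 6), fibroblast (1 and 1 of 5), endothelial (2 and 2 of 5) and histone genes (3 and 5 of 11). The stress response list (12 and 4 of 20) was called only without control replicate 2 (adjusted p = 0.0470) or UHRF1 siRNA replicate 1 (adjusted p = 0.0426). Other SMYD genes (0 and 2 of 3) were too few to test. Adjusted over the list alone, chemokines became 15 and 5, repressive chromatin 10 and 15, cholesterol 12 and 5 and leukocyte markers 3 and 3, and the rest were the same. The largest rises were MMP9, a matrix protease, at 4.56 ± 0.07, GPR132 at 4.53 ± 0.27, ROS1 at 4.41 ± 0.18, S100P at 4.30 ± 0.17 and APOBR at 4.26 ± 0.15. The largest falls besides UHRF1 and GINS2 were ERFE at -6.99 ± 0.30, CCR4 at -4.81 ± 0.20 and TERT, the catalytic part of telomerase, at -4.10 ± 0.22. Ribosomal protein genes took 2.26 ± 0.0853% of reads in control libraries and 1.52 ± 0.105% in UHRF1 siRNA libraries (SD, n = 3 each).

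**Figure D3:**
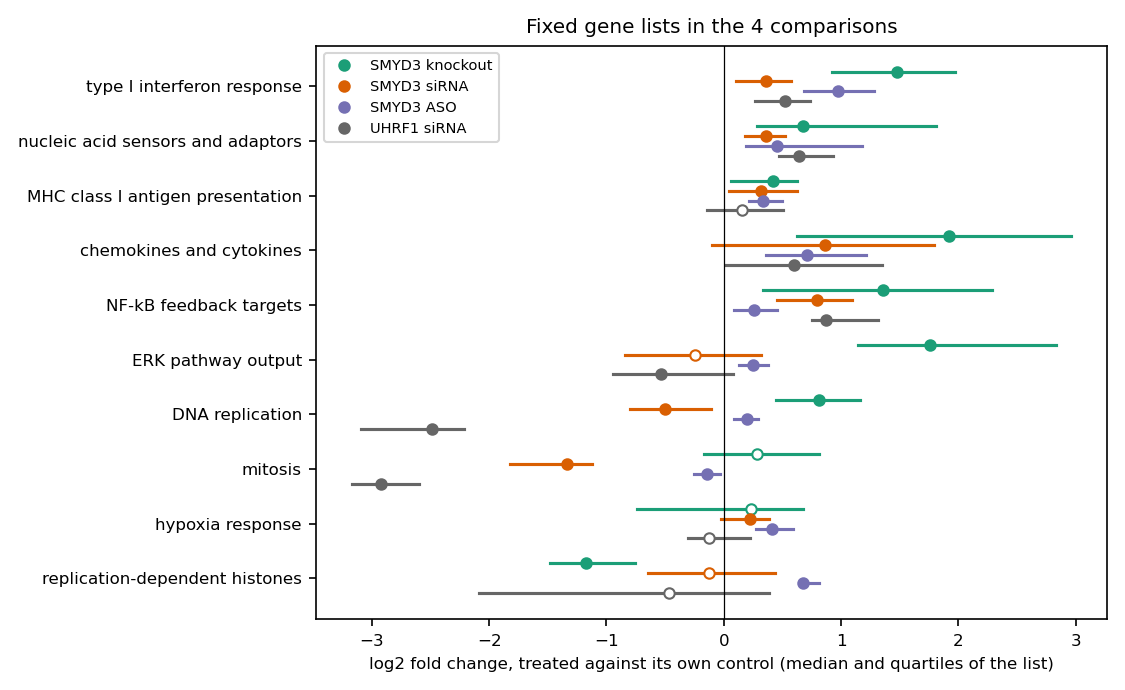
Median (points) and quartiles (lines) of the log2 fold changes (x axis) of 10 of the gene lists (y axis) in the 4 comparisons, each against its own control. Filled points passed camera with the preset correlation; the interferon list lies above 0 in all 4, at 1.47, 0.36, 0.98 and 0.52, while the mitosis list has medians of 0.28, -1.33, -0.14 and -2.92.

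Across the 3 ways of depleting SMYD3, 461 of 15752 genes tested in all were higher in each and 305 lower in each, where independent lists would give 228 and 197. With DESeq2 they were 327 and 139, against 149 and 88.2. With the replicate number as a block they were 756 and 528, against 399 and 355. Of the 50 interferon response genes 30 were higher in all 3, beside 7 of 21 MHC class I genes and 8 of 19 chemokines and cytokines. The genes with the largest shared rise were CXCL10, CXCL11, SERPINB2, OR52K3P, TNFSF13B, GBP5, RSAD2, GBP1P1, ADGRG7 and CXCL1. This ranking set no further limit on expression. SERPINB2 had 6 reads over the control and 48 over the SMYD3 siRNA libraries, and 38 over the PBS and 115 over the ASO libraries. CXCL10 rose by 5.64 in the knockout, 2.54 with the siRNA and 3.45 with the ASO. GBP5, an interferon-induced GTPase, rose by 5.64, 1.38 and 2.10. Besides SMYD3, the largest shared falls were VASH1, LXN, TBC1D26, PDE4DIPP6, TM4SF1-AS1, STAU2-AS1, RHOBTB1, NAPA-AS1 and TP53I11. With the ASO, LXN, TBC1D26 and STAU2-AS1 were near the threshold by edgeR (adjusted p = 0.0373, 0.0470 and 0.0347). VASH1, an inhibitor of blood vessel growth, changed by -3.14, -1.39 and -1.20. With the UHRF1 siRNA, 258 of the 461 shared rises were also higher and 143 lower. Of 300 shared falls tested, 125 were lower and 96 higher. Among all 15958 genes tested there and in the knockout, 5427 were higher and 5659 lower with the UHRF1 siRNA. The counts in the opposite direction thus lay near the share over all genes.

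Across genes, which are not independent replicates, log2 fold changes of the knockout and the ASO had Pearson's r of 0.31 and Spearman's rho of 0.28, the highest of 6 pairs. Between the SMYD3 siRNA and the ASO r was 0.05 and rho 0.01, and between the SMYD3 and UHRF1 siRNAs r was 0.22 and rho 0.20. The knockout had r of 0.11 (rho 0.15) with the SMYD3 siRNA and -0.04 (rho -0.03) with the UHRF1 siRNA, and the ASO had -0.02 (rho -0.06) with the UHRF1 siRNA. Among genes at a mean log2 CPM of 3 or more, the knockout and the SMYD3 siRNA had r of 0.19 (rho 0.22), and the SMYD3 siRNA and the ASO had r of 0.000211 and a rho that turned to -0.06. Genes higher with both the SMYD3 siRNA and the ASO numbered 625 against 510 expected (Fisher's exact test, adjusted p = 9.07e-10). Genes lower with both numbered 486 against 474 (adjusted p = 0.416). But genes higher with the SMYD3 siRNA and lower with the ASO numbered 646 against 461 (adjusted p = 4.51e-24), and the reverse 581 against 525 (adjusted p = 0.00249). Genes higher with both siRNAs numbered 2108 against 1429 (adjusted p = 3.50e-136) and lower with both 2063 against 1460 (adjusted p = 5.90e-107). Genes higher with the ASO and lower with the UHRF1 siRNA numbered 882 against 701 (adjusted p = 1.34e-18). The reverse numbered 763 against 600 (adjusted p = 4.26e-17). Genes higher with the ASO and the UHRF1 siRNA numbered 775 against 680 (adjusted p = 3.01e-06), and lower with both 596 against 618. In the knockout, genes higher there and lower with the UHRF1 siRNA numbered 2730 against 2464 (adjusted p = 1.34e-18), and the reverse 2115 against 2256. Those higher in the knockout and with the UHRF1 siRNA numbered 2607 against 2363 (adjusted p = 2.90e-16), and lower with both 2135 against 2352.5. The knockout and the ASO shared 1381 genes higher against 871 (adjusted p = 5.94e-132) and 945 lower against 745 (adjusted p = 9.12e-24). For the knockout and the SMYD3 siRNA these were 2363 against 1796 (adjusted p = 5.28e-93) and 2098 against 1800 (adjusted p = 1.59e-26). In both pairs the opposite directions lay below the expected numbers. The 4 tables had different controls and did not list the same genes, so each log2 fold change stands against its own control alone.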

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

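The tests of UHRF1 as a cell-cycle gene, of its read number, of a deeper knockdown and of a response to the oligonucleotide were chosen after their results had been seen; the others were set beforehand. Differences below are those of log2 fold changes, the former comparison minus the latter, each tested as a contrast.

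The change differed between comparisons in 12849 of 17079 genes for the knockout and the SMYD3 siRNA, in 12166 for the knockout and the ASO, in 6835 of 16691 for the SMYD3 siRNA and the ASO, and in 9743 for the SMYD3 and UHRF1 siRNAs. For SMYD3 itself the difference was 0.56 for knockout minus SMYD3 siRNA, 0.74 for knockout minus ASO and -1.84 for SMYD3 siRNA minus UHRF1 siRNA. For UHRF1 it was 1.87 for knockout minus SMYD3 siRNA, -2.04 for SMYD3 siRNA minus ASO and 3.17 for SMYD3 siRNA minus UHRF1 siRNA.

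The lists whose change differed by camera with the preset correlation have these median differences. For knockout minus SMYD3 siRNA they were 1.18 for the interferon response, -1.09 for MHC class II, 0.96 for chemokines, 0.85 for checkpoint ligands, 1.36 for DNA replication, 1.66 for mitosis, 1.06 for basal genes, 0.68 for the stress response, 2.11 for ERK output and -0.97 for histones. For knockout minus ASO they were 0.45 for the interferon response, 1.12 for chemokines, 0.65 for DNA replication, 1.00 for NF-kB, 0.99 for basal genes, 0.87 for the stress response, 1.64 for ERK output and -1.76 for histones. For SMYD3 siRNA minus ASO they were -0.80 for the interferon response, -0.41 for checkpoint ligands, -0.65 for DNA replication, -1.22 for mitosis, 0.43 for NF-kB, -0.51 for ERK output and -0.80 for histones. For SMYD3 siRNA minus UHRF1 siRNA they were -0.21 for the interferon response, 2.08 for DNA replication and 1.49 for mitosis. With an estimated correlation only histones in knockout minus ASO kept an adjusted p under 0.05.

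Many genes changed by a log2 fold change of 1 or more between the knockout clone and its parental line. Whether the lower mitochondrial share accounts for them through scaling was tested. On recovered reads 99.4% of the genes called so (6251 of 6287) were still called without mitochondrial genes. Both fits used TMM factors, which trim genes with extreme changes or levels, so leaving out mitochondrial genes could change the scaling little. The test therefore does not decide on scaling. Nor can it tell whether the lower share goes with another difference between the lines. Copy-number differences between the lines may be part of the cause. In the knockout 4.74% of the variance of log2 fold changes lay between windows of 5 Mb, against at most 0.833% in 100 shuffles. The share was 2.81% with the SMYD3 siRNA, 1.06% with the ASO and 1.37% with the UHRF1 siRNA. Their shuffles gave at most 0.930%, 0.821% and 0.646%, so a share above the shuffles was not particular to the knockout. The window that holds SMYD3 had a median of 0.73 in the knockout. Whether single listed genes rose there with their neighbours was not tested. Copy-number differences are not the whole cause, as 26.8% of genes in windows with a median near 0 also changed by 1 or more. Loss of SMYD3 and other differences of a single clone cannot be told apart. Of the 5487 genes with such a change in the knockout that were tested in all 3 SMYD3 comparisons, 7.95% were called the same way with both the siRNA and the ASO. That is above the 3.13% of independent lists and far below a majority.

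UHRF1 was lower with the SMYD3 siRNA and higher in the knockout (0.44, or 0.16 with upper quartile factors) and with the ASO. Too few reads did not account for it, as the lowest library of the siRNA table held 96 UHRF1 reads. A candidate explanation is a difference in cell-cycle state, since UHRF1 moved with the DNA replication list and inside the range of its members in 3 of the 3 SMYD3 comparisons. That account is weaker at both ends: with the siRNA only 1 of 36 members fell further than its -1.68, and with the ASO it rose more than 32 of 36 while the mitosis list fell (median -0.14, adjusted p = 8.98e-04, or 0.481 with an estimated correlation). All 36 DNA replication genes also fell with the UHRF1 siRNA, so moving together cannot tell whether UHRF1 or the list changed first. A direct effect of SMYD3 on UHRF1, or of the SMYD3 siRNA on UHRF1, was not tested.

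The interferon list was higher with the ASO than with the SMYD3 siRNA by camera with the preset correlation, but not with an estimated one (adjusted p = 0.330). A knockdown deeper by a log2 fold change of 0.5 or more lay outside the 95% interval of the difference, whose lower bound was -0.47; that limit was set after the values were seen, and a smaller gap stays open. A response to the oligonucleotide itself, given against PBS, cannot be told apart from loss of SMYD3, as the design has no control oligonucleotide. NF-kB feedback genes rose with the ASO (adjusted p = 0.00316, or 0.240 with an estimated correlation) and in the knockout, which had no oligonucleotide (adjusted p = 0.0180, or 0.234), so this list does not decide between them.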

How the results depend on the processing

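The alternatives of edgeR with TMM factors on recovered reads, on pseudocounts and on mitochondrial genes were chosen after seeing the data. So were, for the differences, those on all 22 libraries. The rest were set beforehand. For the knockout the DESeq2, RLE and upper quartile fits also used recovered reads. Against the main limma fit they thus changed the test and the low-count filter as well as the scaling. A test against a log2 fold change of 0.5 called 8625 genes in the knockout, 2273 with the SMYD3 siRNA, 173 with the ASO and 5093 with the UHRF1 siRNA, since it asks for a larger change, and UHRF1 in the knockout (0.44) and with the ASO (0.36) and SMYD3 with the UHRF1 siRNA (-0.57) were no longer called. DESeq2 called 2259 genes with the ASO, 145 of them at an absolute log2 fold change of 1 or more (114 higher and 31 lower), and 466 genes in all 3 SMYD3 comparisons. Without ASO replicate 1 the lower genes at 1 or more with the ASO were 184, against 101. In the knockout the lower genes at 1 or more were 2260 with a filter of 10 in every library, against 3752, and the higher ones 1561 with upper quartile factors, against 2430. The replicate number as a block called 6755 genes with the ASO, where the lower genes at 1 or more were 154, and 1284 in all 3 (756 higher and 528 lower). Deviations of libraries with the same number correlated at -0.0877 to 0.0489 in the knockout, -0.0142 to 0.233 with the SMYD3 siRNA, 0.108 with the ASO and -0.00603 to 0.00935 with the UHRF1 siRNA, and matched their own number best in 0, 2 and 1 of 3 for the knockout, SMYD3 siRNA and UHRF1 siRNA. A pairing is not stated in the labels, and with the SMYD3 siRNA and the ASO the values leave it open. The library codes in the titles alternate between control and treated for the SMYD3 siRNA and the ASO, and run group by group for the others. With an estimated correlation the lists called were 0 in the knockout, 0 with the SMYD3 siRNA, 0 with the ASO and 1 with the UHRF1 siRNA, and the interferon list had adjusted p = 0.503, 0.534, 0.240 and 0.135. Fry called 23 lists in the knockout and 22 with the UHRF1 siRNA, and turned the direction of keratinocyte differentiation in the knockout (0.0133) and of checkpoint ligands (0.0243) and fibroblast markers (0.00566) with the UHRF1 siRNA, none called by camera. For the interferon list fry gave adjusted p = 8.70e-05 in the knockout, 0.00330 with the SMYD3 siRNA, 0.00504 with the ASO and 2.15e-05 with the UHRF1 siRNA. With the SMYD3 siRNA it gave adjusted p = 0.0049 for mitosis and 0.0232 for DNA replication. Among genes at a mean log2 CPM of 3 or more, r became 0.19 for knockout and SMYD3 siRNA, 0.28 for knockout and ASO, 0.000211 for SMYD3 siRNA and ASO and 0.24 for the siRNAs. Apart from those of fewer genes or a stricter test, the cause was not tested. Without 1 library the genes called ranged from 12918 to 13954 in the knockout, from 7663 to 9189 with the SMYD3 siRNA, from 2738 to 4118 with the ASO (where the lone library of a group is assumed to vary like the others) and from 11305 to 11624 with the UHRF1 siRNA. Of 5850 values of named genes 5629 kept their direction and side of the threshold, 218 were no longer called and 3 became called; of 772 values of other lists the numbers were 688, 51 and 30. Depth was 24777802 reads or more in every library.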

Other observations

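The test of the splits was set beforehand. Each comparison of 3 libraries against 3 allows 10 splits, too few for a share under 0.05. The real split called 14341 genes in the knockout, 9214 with the SMYD3 siRNA and 11859 with the UHRF1 siRNA, and the highest of the other splits called 0 genes in each; 1 of the 10 splits, the real one, gave as many in each.

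With the UHRF1 siRNA KRT17 and KRT16, keratins of activated epithelium, rose by 3.55 ± 0.06 and 2.16 ± 0.08, while the integrin ITGA6 fell by 1.06 ± 0.05. AREG rose by 4.18 ± 0.11 in the knockout and fell by 1.48 ± 0.07 with the UHRF1 siRNA, and this difference was not tested. CCND1, cyclin D1, fell by 1.64 ± 0.08 with the SMYD3 siRNA. In the histone list H2BC21 rose by 2.68 ± 0.05 with the UHRF1 siRNA while H2BC12 fell by 2.68 ± 0.06.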
